A study of Mus musculus with 9 samples.

How the data were processed

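RNA from mouse embryonic stem cell cultures differentiated to cardiomyocytes was measured on 9 one-colour 3 prime expression arrays, 3 each at day 10, 20 and 30, with groups and replicate numbers taken from the sample labels. Per the labels' protocols, the cells carry puromycin resistance under the Ncx1 promoter, puromycin was given from day 7, RNA was taken up in TRIzol, and it was amplified and labelled with biotin by a kit that primes from the 3 prime end. The values are the log2 signals deposited by the authors, 1 per probe set and array. How they were normalized and the base of the logarithm are not given in the sources used here. The base was inferred from the values, which run from 2.77 to 14.52, and the array medians lay within 0.07 of each other, so the values were used as deposited. Scanner files were not used here, so background could not be judged probe by probe. No genome build was named, so no coordinates are given.

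Of 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 had none, and 64 were array controls. Of those with 1 symbol, 34754 were found in the reference table by gene identifier, and 0 symbols differed. Only probe sets with 1 symbol were named. A gene was represented by its probe set with the highest mean over the 9 arrays. This gave 18193 genes, of which 9012 had at least 2 probe sets, and no gene was filtered out for low signal.

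The samples and groups, the tests, the gene lists, the rule for named genes and the alternative settings were chosen before the data were examined, except where said below. A model with a mean for each day was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual and 2.18 prior degrees of freedom), so that all days share an estimate of the spread. The contrasts were day 20 minus day 10, day 30 minus day 20, day 30 minus day 10, and the later change minus the earlier change, and a moderated F test covered all days. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes, and the threshold was an adjusted p of 0.05. A call at least 2-fold also had a log2 difference of at least 1.

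There were 32 gene lists fixed in advance with 582 genes, of which 540 were measured. They covered sarcomere, fetal heart genes, calcium handling, ion channels of the working myocardium, pacemaker, ventricular and atrial genes, cardiac transcription factors, fatty acid oxidation, lipid uptake and PPAR targets, oxidative phosphorylation, citric acid cycle, glycolysis, cell cycle, imprinted growth genes, cytokine and growth signalling, hypoxia, unfolded protein and amino acid stress, p53, interferon, cholesterol synthesis, antioxidant response, ribosomal proteins and pluripotency. Other lists held markers of endoderm, neural cells, fibroblasts and matrix, smooth muscle, endothelium, epicardium, blood and skeletal muscle. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera with a correlation estimated from the data, and fry, were alternatives. Camera compares a list with all other genes, while fry tests only whether the list's own genes move one way. Member counts are given over all genes and adjusted over the list alone.

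The genes named for day 30 against day 10 are the 10 that rose most and the 10 that fell most among those past the threshold whose arrays did not overlap between the days and whose higher mean exceeded the median of all genes (6.63). The other 2 contrasts of days name 5 and 5 by the same rule, and the difference between intervals 3 and 3. Each list names up to 4 members in order of adjusted p in day 30 against day 10. Myh6, Myh7, Tnni1, Tnni3, Myl2, Myl7, Slc8a1, Nppa, Mki67 and Ppargc1a are always named, a member of an isoform pair is named with its pair, and a probe set with no symbol or several is never named. Pairs of isoform genes and control probe sets were tested over the 3 days with an exact permutation test of the one-way F statistic over the 280 distinct splits, adjusted over the 5 pairs measured.

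The fit was tested on simulated data for day 30 against day 10 with 18193 genes. It recovered 61 of 100 genes changed 2-fold and 88 of 100 changed 4-fold, with 9 false calls among 158. With no change simulated, it called 0 genes for day 30 against day 10, 1 over any days and 1 between intervals. A list shifted by 0.5 was recovered, and 0 other lists were called. The simulated genes varied independently, whereas the correlation estimated from the real arrays was 0.87 for the cell cycle list. They also had the same spread at every day, whereas the real day 10 arrays varied more. The simulation therefore cannot show how often lists of correlated genes are called falsely, or how the unequal spread affects the calls of genes. Alternatives included other normalizations, filters on dim genes, other ways to represent a gene, array weights, fits of only the days compared, the replicate number as a block, other list tests, and leaving out each array in turn. A fit with the poly-A spike level as a covariate, and a test of the lists for the difference between intervals, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.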

Results

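Gene expression was measured in cardiomyocytes made from mouse embryonic stem cells, at 3 ages of the culture: day 10, day 20 and day 30 of differentiation, with 3 arrays at each age. The cells came from a line derived from R1 embryonic stem cells that carries a puromycin resistance gene under the promoter of Ncx1, a sodium-calcium exchanger gene listed here as Slc8a1. Differentiation was driven by activin A, BMP4, VEGF, bFGF and FGF10, and puromycin was added from day 7 to remove cells that did not use this promoter. Total RNA was labelled with biotin and hybridised to 3 prime expression arrays, so that each array gives 1 log2 signal per probe set. The stated purpose was to see how mature such cardiomyocytes become in culture, and the comparisons below are therefore between the 3 ages. The labels do not say whether the replicates of an age were separate differentiations, so that p-values measure the spread between these samples, which may be technical. The 9 arrays limit the precision, and 18193 genes were tested.

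The arrays separated by age on the first principal component, which held 59.6% of the variance. Day 10 arrays lay between -73.2 and -48.0 on it, day 20 arrays between 15.6 and 26.8, and day 30 arrays between 36.9 and 48.7. The second component, with 14.3% of the variance, spread the day 10 arrays from 31.9 (replicate 1) to -41.2 (replicate 3). Day 10 arrays differed more among themselves than the later ones: the median SD of a gene over 3 arrays was 0.187 at day 10, 0.130 at day 20 and 0.137 at day 30 (log2), and the lowest correlation between 2 arrays of an age was 0.965, 0.987 and 0.986. The poly-A spikes, control RNAs added before labelling, had a mean log2 signal of 5.24 in day 10 replicate 2 and 5.09 in day 10 replicate 3, against 5.91 to 6.69 in the other 7 arrays. Their means by age were 5.52 ± 0.62, 6.40 ± 0.25 and 6.05 ± 0.16 (SD, n = 3, exact permutation p = 0.0786). In day 30 replicate 2, the 18S ribosomal RNA signal was 10.27 (log2), against 12.07 to 13.44 elsewhere, and the 3 prime minus 5 prime difference of the beta-actin control probe sets was 0.79, the highest of the 9 arrays. That difference averaged 0.34 ± 0.14, 0.47 ± 0.12 and 0.52 ± 0.24 at the 3 ages (SD, n = 3, exact permutation p = 0.486), and the same difference for Gapdh averaged -0.17 ± 0.04, -0.17 ± 0.03 and -0.11 ± 0.14 (SD, n = 3, exact permutation p = 0.768).

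**Figure D1:**
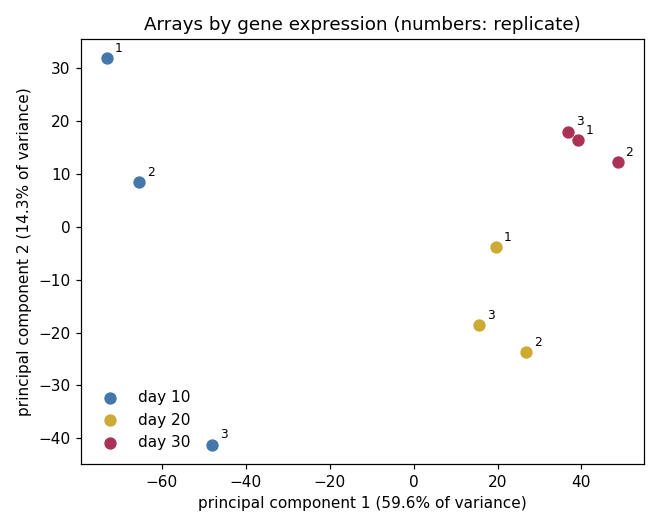
Principal components of the 9 arrays over all genes tested, with component 1 (59.6% of the variance) on the horizontal axis and component 2 (14.3%) on the vertical axis; each point is an array, coloured by age and numbered by replicate. The 3 ages lie apart on component 1, and the day 10 arrays are spread from 31.9 to -41.2 on component 2.

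The comparison of day 30 with day 10 spans the whole period sampled. The gene with the highest rise was Fmod, which encodes the collagen-binding proteoglycan fibromodulin. It rose from 4.10 ± 0.37 to 12.93 ± 0.37 on the log2 scale (SD, n = 3), a difference of 8.83 (SE 0.41, adjusted p = 2.9e-05). Penk, which encodes the opioid peptide precursor proenkephalin, rose by 7.72 (adjusted p = 6.1e-05). Comp, a cartilage matrix protein gene, rose by 7.71 (SE 0.26, adjusted p = 1.5e-05), and Lum, which encodes the matrix proteoglycan lumican, rose by 7.57 (SE 0.65, adjusted p = 0.00032). The other genes among the 10 with the highest rises were Aspn (7.44), Ecrg4 (6.99), Fbln5 (6.96), Abi3bp (6.87), Lox (6.83) and Dcn (6.73). The deepest fall was that of Hmga2, a chromatin protein gene of embryonic cells, which fell by 4.78 (SE 0.19, adjusted p = 2.1e-05), from 9.60 ± 0.22 to 4.83 ± 0.13 (SD, n = 3). Below it stood Bex4 (-4.43), Podxl (-4.43), the keratin genes Krt18 (-4.18) and Krt8 (-3.58), Akap5 (-4.10), the proto-oncogene Mycn (-3.97), Rps6ka6 (-3.74), Sox11 (-3.72) and Tdgf1 (-3.48), a Nodal co-receptor gene of pluripotent cells. In all 20 of these genes the 3 arrays of day 30 lay wholly above or wholly below those of day 10, as the rule for choosing them required, and chance alone gives such a separation to 10% of genes.

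Some heart genes rose. Of the 25 measured sarcomere genes, 6 rose and none fell (6 and 0 when adjusted over the list alone), with a median change of 0.39. Among them were Tnni3, the adult cardiac troponin I gene, at 2.85 (SE 0.31, adjusted p = 0.00088), Myom2, an M-band gene, at 5.41 (SE 0.61, adjusted p = 0.00094), Myoz2 at 3.16 and Tcap at 1.78. The list as a set was shifted upward (camera adjusted p = 0.00044), but adjusted p = 0.45 with an estimated correlation. The myosin heavy chain genes, both near the top of the signal range, did not pass the test. Myh6 differed by 0.41 (adjusted p = 0.17; 95% interval -0.03 to 0.85) and Myh7 by 0.50 (adjusted p = 0.19; -0.07 to 1.07). Nor did the ventricular light chain Myl2 (1.49, adjusted p = 0.16), the atrial light chain Myl7 (-0.08, adjusted p = 0.77) or the natriuretic peptide gene Nppa (2.98, adjusted p = 0.17), whose values spanned 6.05 to 11.62 among the day 10 arrays. Without day 10 replicate 3, Myh6 (0.60, adjusted p = 0.026), Myh7 (0.78, adjusted p = 0.016) and Nppa (4.29, adjusted p = 0.034) passed. Myh6 was at 0.19 without day 10 replicate 1 and 0.02 with the mean of its probe sets, and Nppa at 1.51 without day 10 replicate 2. Myl7 was at -0.23 and -0.20 without day 10 replicate 1 or day 30 replicate 3, and at 0.04 and 0.02 without day 10 replicate 3 or day 30 replicate 1. Of 17 calcium handling genes, 6 rose and 1 fell (7 and 2 when adjusted over the list alone, median 0.58, adjusted p = 0.016, adjusted p = 0.45 with an estimated correlation). Casq2, the cardiac calsequestrin gene, rose by 6.16 (SE 0.23, adjusted p = 1.5e-05), Pln, which encodes the calcium pump regulator phospholamban, rose too (adjusted p = 0.0077), Trdn by 2.23 and S100a1 by 1.95. Slc8a1, whose promoter drove the selection, measured 9.63 ± 0.38, 8.17 ± 0.20 and 8.50 ± 0.83 at day 10, 20 and 30 (SD, n = 3), and its difference between day 30 and day 10 was -1.13 (adjusted p = 0.073, -1.53 with adjusted p = 0.021 without day 30 replicate 1, -0.70 without day 30 replicate 2, and -0.26 with the mean of its probe sets). Of 15 ion channel and pump genes of the working myocardium, 7 rose and none fell, also when adjusted over the list alone (median 0.68, adjusted p = 0.00044, adjusted p = 0.18 with an estimated correlation), with the potassium channel genes Kcnq1 at 2.60, Kcnd2 at 2.66 and Kcnj3 at 4.06. In the ventricular list 3 of 8 genes rose (Pln, Irx4, Lbh, 3 also over the list alone, median 1.09, adjusted p = 0.011, adjusted p = 0.41 with an estimated correlation). In the atrial list 3 of 10 rose (Nr2f2, Kcnj3, Sln, 3 also over the list alone, median 0.40, adjusted p = 0.049, adjusted p = 0.40 with an estimated correlation). The atrial list missed the threshold without day 10 replicate 1, day 10 replicate 3 or day 30 replicate 3 (highest adjusted p = 0.11). Lbh missed it without each of 7 arrays, all but day 10 replicate 3 and day 30 replicate 1 (highest adjusted p = 0.12), and Irx4 without each of 3 (highest adjusted p = 0.084). The sarcomere median was 0.19 without day 10 replicate 1 and 0.605 without day 10 replicate 3. Without day 10 replicate 3 the calcium handling median was 0.91 and that of ion channels 1.04. The atrial median was 0.25 without day 10 replicate 1, 0.60 without day 10 replicate 2 and 0.64 without day 30 replicate 1. In these same arrays the poly-A spike level of day 10 was 0.53 below that of day 30, and the fibroblast and matrix list stood 3.44 higher at day 30.

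**Figure D2:**
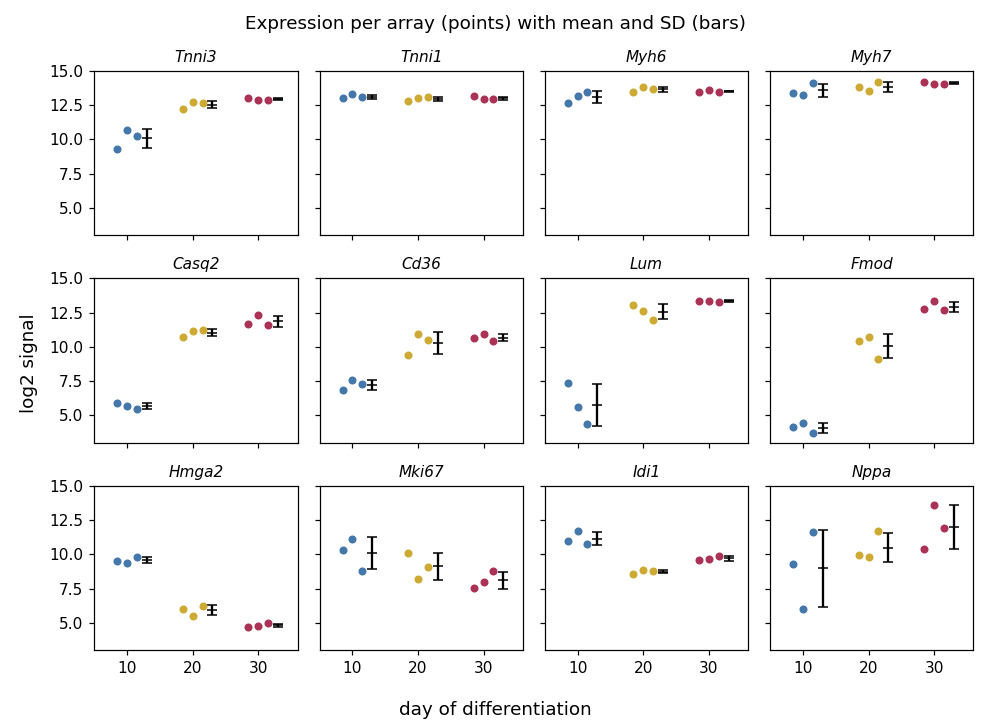
Log2 signal (vertical axis) of 12 genes at day 10, 20 and 30 of differentiation (horizontal axis); each point is an array, and the bar beside each age is the mean with its SD (n = 3). Casq2 rises from 5.69 to 11.86 and Fmod from 4.10 to 12.93, Hmga2 falls from 9.60 to 4.83, and the day 10 arrays of Nppa are spread from 6.05 to 11.62.

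The lists of fatty acid oxidation and lipid uptake were shifted upward and that of cholesterol synthesis downward. Of 19 fatty acid oxidation genes, 10 rose and none fell (12 over the list alone, median 0.48, adjusted p = 3.2e-06, adjusted p = 0.41 with an estimated correlation). Acadl and Acadvl, which encode acyl-CoA dehydrogenases, rose by 1.19 and 1.41, Cpt1a, the gene of the liver form of the mitochondrial carnitine transferase, by 1.23 and Acot2 by 1.15. Of 18 genes of lipid uptake and PPAR targets, 8 rose and 1 fell (11 and 1 when adjusted over the list alone, median 0.53, adjusted p = 0.00018, adjusted p = 0.18 with an estimated correlation). Among them were the fatty acid transporter gene Cd36 at 3.45, the lipase gene Lpl at 2.12, Ppara at 2.58 and Slc27a1 at 1.33. Ppargc1a, a regulator of mitochondrial genes, differed by 0.29 (adjusted p = 0.17), and by 0.19 and 0.18 without day 10 replicate 1 or day 30 replicate 1. In the oxidative phosphorylation list 6 of 39 genes rose, also over the list alone, with a median of 0.11 (adjusted p = 0.0093, adjusted p = 0.73 with an estimated correlation). Its members with the highest changes named by the rule, Cox8b (3.25) and Cox6a2 (2.07), encode the heart and muscle forms of subunits of cytochrome c oxidase. This list missed the threshold without day 10 replicate 1 or day 30 replicate 1 (highest adjusted p = 0.19, lowest median 0.04 without day 30 replicate 1, highest 0.20 without day 30 replicate 2, 0.17 without day 10 replicate 3), and Cox6a2 without day 30 replicate 1 (adjusted p = 0.060). The citric acid cycle (median 0.08, adjusted p = 0.56, from 0.01 without day 30 replicate 1 to 0.17 without day 30 replicate 2) and glycolysis lists (3 rose and 2 fell of 20, median 0.30, adjusted p = 0.12) were not shifted, and the glycolysis median depended on the array left out: -0.02 without day 10 replicate 1, 0.18 without day 30 replicate 1, and 0.44 and 0.47 without day 10 replicate 2 or 3, where it passed (adjusted p = 0.045 and 0.016). Of 16 cholesterol synthesis genes, 12 fell and none rose (14 over the list alone, median -1.04, adjusted p = 3.2e-06, adjusted p = 0.41 with an estimated correlation). Among them were Idi1 (-1.44), Mvd (-1.34), Sc5d (-1.10) and Hmgcs1 (-0.94).

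The cell cycle and pluripotency lists were shifted downward. Of 42 cell cycle genes, 17 fell and none rose over all genes, and 35 fell when adjusted over the list alone, with a median of -1.99 (adjusted p = 1.4e-09, adjusted p = 0.45 with an estimated correlation). The replication licensing genes Mcm2 (-2.23) and Mcm7 (-2.03) were among them. Relative to the mean over the 9 arrays, the list's median was 1.52, 1.90 and -0.25 in day 10 replicates 1, 2 and 3. It was -1.32, -1.13 and -0.32 in those of day 30, so that day 10 replicate 3 lay close to day 30 replicate 3. Mki67, the proliferation marker, differed by -1.98 (adjusted p = 0.071, and -2.61 with adjusted p = 0.015 without day 10 replicate 3), with day 10 replicate 3 at 8.83 and the other day 10 arrays at 10.30 and 11.12. Of 16 pluripotency genes, 8 fell and 2 rose, also over the list alone (median -0.44, adjusted p = 0.0069, adjusted p = 0.45 with an estimated correlation). Falls were those of Sall4 (-2.61), Pou5f1 (-2.17, to a day 30 level of 3.80) and Dppa4 (-1.16). Klf2, a gene that endothelial cells also use, rose by 2.47. Of 15 growth signalling genes, 6 fell and 2 rose, also over the list alone (median -0.15, mean -0.91, adjusted p = 0.012, adjusted p = 0.18 with an estimated correlation). Among them were the RNA-binding protein genes Igf2bp1 (-2.87) and Igf2bp3 (-2.17). Without day 10 replicate 1 the pluripotency median was -0.73 and that of growth signalling -0.34. In the neural list 5 of 14 genes fell (6 over the list alone, median -0.37, adjusted p = 0.011, adjusted p = 0.18 with an estimated correlation). In the ribosomal protein list 5 of 21 fell (7 over the list alone, median -0.22, adjusted p = 0.00056, adjusted p = 0.34 with an estimated correlation), with Rpl14 at -1.53 and Rpl8 at -0.38. Of 14 imprinted growth genes 5 fell and 2 rose (6 and 3 over the list alone, median -0.27, adjusted p = 0.20, -0.18 and -0.45 without day 10 replicate 1 or 3), with Cdkn1c at -1.65 and Dlk1 at 1.77. The endoderm list had 4 falls and 1 rise among 17 genes, also over the list alone (median -0.17, adjusted p = 0.081), and it passed without day 10 replicate 1, day 10 replicate 2 or day 30 replicate 3 (lowest adjusted p = 0.046, median -0.07 without day 10 replicate 1). Its rise was Epcam, at 1.49 with the brightest probe set and -0.0014 with the mean of its probe sets.

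Lists of markers of other cell types were tested as well. Of 22 fibroblast and matrix genes, 18 rose and none fell (20 over the list alone), with a median of 3.44 (adjusted p = 3.5e-15, adjusted p = 0.18 with an estimated correlation). Col6a3 rose by 6.12, Bgn by 5.31 and Col5a2 by 3.90. The smooth muscle list had 3 rises and 2 falls among 13 genes (5 and 2 over the list alone, median 0.77, adjusted p = 0.21), with Pdgfrb rising by 3.15 and with Cnn1 at -2.75 and Acta2 at -1.04. Medians were -0.24 in the endothelial list (2 rose and 2 fell of 17, adjusted p = 0.66) and 0.20 in the epicardial list (1 and 1 of 13, adjusted p = 0.47). They were -0.01 in the blood list (1 and 1 of 16, adjusted p = 0.76, mean 0.12) and -0.10 in the skeletal muscle list (1 and 1 of 17, adjusted p = 0.77, mean 0.09). Single arrays turned the sign of all 4 medians. The endothelial median was 0.05 without day 10 replicate 3 and -0.14 without day 30 replicate 1. The epicardial median was -0.11 without day 10 replicate 3, -0.05 without day 30 replicate 2, and 0.46, 0.45 and 0.57 without day 10 replicate 1, day 30 replicate 1 or day 30 replicate 3. The blood median ran from -0.05 (without day 10 replicate 3) to 0.03 (without day 10 replicate 1), and the skeletal muscle median was 0.01 without day 30 replicate 1, -0.01 without day 30 replicate 2, and -0.04 and -0.05 without day 10 replicate 1 or 3. Of 16 hypoxia response genes, 6 rose and none fell (8 over the list alone, median 1.11, adjusted p = 0.00094, adjusted p = 0.45 with an estimated correlation). Among them were Car9 (5.26), Egln3 (4.31) and the collagen hydroxylase genes P4ha2 (1.95) and P4ha1 (1.34). Of 18 interferon response genes, 5 rose and none fell (9 over the list alone, median 0.41, adjusted p = 0.00056, adjusted p = 0.18 with an estimated correlation), with Xaf1 at 2.53 and Ifi35 at 2.14. In the list of unfolded protein and amino acid stress 6 of 17 genes rose, also over the list alone (median 0.41, adjusted p = 0.023, adjusted p = 0.41 with an estimated correlation). Chac1 rose by 3.40 and Trib3 by 2.39, and the list's adjusted p was 0.17 and its median 0.26 without day 10 replicate 3, while the hypoxia median was 0.64 without day 10 replicate 1. The antioxidant list (2 rose of 14, Nqo1 at 2.70 and Gstm1 at 1.93, median 0.27, adjusted p = 0.12) and the p53 list (1 rose of 13, Fas, median -0.34, adjusted p = 0.75) were not shifted. The same held for the pacemaker (1 rose of 12, Cacna1g at 4.18, median 0.06, adjusted p = 0.47), cardiac transcription factor (2 rose of 18, Mef2a and Nfatc1, median -0.27, mean 0.10, adjusted p = 0.75) and fetal heart gene lists (1 rose and 1 fell of 11, Sln and Acta2, median 0.08, adjusted p = 0.77). Over the list alone, the counts of these 5 lists were the same, and the antioxidant list passed without day 10 replicate 1 (median 0.25, adjusted p = 0.026), with medians of 0.17 and -0.06 without day 10 replicate 2 or 3 and 0.12 without day 30 replicate 1. The cardiac transcription factor median was 0.12 without day 10 replicate 2 and -0.09 without day 10 replicate 3 or day 30 replicate 1, and the p53 median -0.11 without day 10 replicate 1. The fetal heart gene median was -0.04 without day 10 replicate 2, 0.04 without day 10 replicate 3 and -0.08 without day 30 replicate 2. The pacemaker median was 0.11 without day 10 replicate 2, 0.03 without day 10 replicate 3 or day 30 replicate 1, and -0.05 without day 30 replicate 2.

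Over all genes, 3841 of 18193 passed the test between day 30 and day 10, of which 2036 were higher and 1805 lower at day 30, and 1628 of them differed at least 2-fold (1096 higher, 532 lower). Array weights gave 6126, with weights of 0.47, 2.68 and 0.29 for day 10 replicates 1, 2 and 3. The day 10 mean then rests largely on replicate 2. The test was limma's moderated test on all 9 arrays with Benjamini-Hochberg adjustment at 0.05. It uses a spread shared by all days, although the day 10 arrays varied more. A fit of only the arrays of these days gave 2654. Of the 32 gene lists, 18 were shifted with a preset correlation of 0.01 (12 up, 6 down) and 0 with an estimated correlation, where 6 lists had an unadjusted p under 0.05. By fry, which asks whether a list's own genes move one way, 20 lists passed. Folds near background are compressed on such arrays, which applies to genes such as Fmod, at 4.10 on day 10.

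The comparison of day 20 with day 10 covers the first 10 days sampled. Lum rose by 6.79 (SE 0.65, adjusted p = 0.0010), Fbln5, which encodes a protein of elastic fibres, by 6.74 (SE 0.54, adjusted p = 0.00049), Lox, the gene of a collagen and elastin cross-linking enzyme, by 6.55, Mgp by 6.23 and Fmod by 5.99. The deepest falls were those of Tdgf1 (-3.74), Hmga2 (-3.67), Krt18 (-3.58), Podxl (-3.26) and Tagln3 (-3.06). Of the 22 fibroblast and matrix genes 14 rose (15 over the list alone, median 2.39, adjusted p = 7.6e-13, adjusted p = 0.26 with an estimated correlation). Of the 16 cholesterol synthesis genes 13 fell (15 over the list alone, median -1.39, adjusted p = 1.6e-10, adjusted p = 0.34 with an estimated correlation), with Idi1 at -2.42. Hypoxia response genes rose in 7 of 16 cases (10 over the list alone, median 1.43, adjusted p = 1.2e-06, adjusted p = 0.39 with an estimated correlation). Tnni3 rose by 2.45 (SE 0.31, adjusted p = 0.0034), Casq2 by 5.35 and Myom2 by 5.39. Slc8a1 fell by 1.46 (adjusted p = 0.041), a call that was lost without each of 7 arrays (highest adjusted p = 0.13). Krt18 lost its call without any of the 3 day 20 arrays (highest adjusted p = 0.065) and Tdgf1 without day 20 replicate 2 (adjusted p = 0.060).

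In the first 10 days 4 of the 8 heart lists were shifted upward. In the sarcomere list 6 of 25 genes rose, and 7 when adjusted over the list alone (median 0.29, adjusted p = 0.0041, adjusted p = 0.58 with an estimated correlation). In calcium handling 5 of 17 genes rose and 1 fell, and 6 and 1 over the list alone (median 0.62, adjusted p = 0.0056, adjusted p = 0.47 with an estimated correlation). Of the 15 ion channel genes 6 rose, and 7 over the list alone (median 0.97, adjusted p = 0.00024, adjusted p = 0.26 with an estimated correlation). Of the 8 ventricular genes 3 rose, also over the list alone (median 1.04, adjusted p = 0.011, adjusted p = 0.39 with an estimated correlation). The other 4 heart lists were not shifted, namely the atrial (median 0.49, adjusted p = 0.094), pacemaker (median 0.01, adjusted p = 0.38), cardiac transcription factor (median 0.03, adjusted p = 0.51) and fetal heart gene lists (median -0.14, mean 0.29, adjusted p = 0.98). Of the 5 metabolic lists for fuel use, 4 were shifted upward, and the citric acid cycle list, with 0 members past the test in limma, was not (median 0.12, adjusted p = 0.24, 0.0499 without day 10 replicate 3, median 0.04 without day 10 replicate 1 and 0.07 without day 20 replicate 3). Fatty acid oxidation had 6 rises among 19 genes, and 11 over the list alone (median 0.44, adjusted p = 7.5e-07, adjusted p = 0.39 with an estimated correlation). Lipid uptake had 4 rises among 18 genes, and 6 rises and 1 fall over the list alone (median 0.44, adjusted p = 0.00023, adjusted p = 0.26 with an estimated correlation). Glycolysis had 3 rises among 20 genes, also over the list alone (median 0.55, adjusted p = 0.0019, adjusted p = 0.58 with an estimated correlation). Oxidative phosphorylation had 3 rises among 39 genes, and 1 over the list alone (median 0.13, adjusted p = 0.0091, adjusted p = 0.72 with an estimated correlation). Further lists were shifted downward. In the cell cycle list 2 of 42 genes fell, and 0 over the list alone by limma (median -1.21, adjusted p = 6.4e-06, adjusted p = 0.58 with an estimated correlation). In the pluripotency list 8 of 16 genes fell and 1 rose, and 10 and 1 over the list alone (median -0.45, adjusted p = 0.00053, adjusted p = 0.39 with an estimated correlation). In the neural list 4 of 14 genes fell, and 5 over the list alone (median -0.36, adjusted p = 0.0056, adjusted p = 0.26 with an estimated correlation). Growth signalling had 5 falls and 1 rise among 15 genes, and 6 and 1 over the list alone (median -0.22, adjusted p = 0.036, adjusted p = 0.31 with an estimated correlation). Ribosomal proteins had 2 falls among 21 genes, also over the list alone (median -0.11, adjusted p = 0.034, adjusted p = 0.47 with an estimated correlation). Growth signalling missed the threshold without day 10 replicate 3 (adjusted p = 0.13), ribosomal proteins without that array or day 20 replicate 3 (highest adjusted p = 0.16), and oxidative phosphorylation without day 10 replicate 1 or day 20 replicate 3 (highest adjusted p = 0.085). The cell cycle median was -0.68 without day 10 replicate 2, -0.73 without day 20 replicate 2 and -1.87 without day 10 replicate 3. Of the heart lists not shifted, 3 had medians whose sign depended on single arrays. The fetal heart gene median was 0.11 without day 10 replicate 3 and between -0.05 and -0.08 without any other day 10 or day 20 array. The cardiac transcription factor median was -0.12 without day 10 replicate 1, -0.02 without day 10 replicate 3, 0.08 without day 20 replicate 1 and -0.18 without day 20 replicate 2. The pacemaker median ran from -0.11 without day 10 replicate 1 to 0.21 without day 10 replicate 2. The sarcomere median was 0.17 without day 10 replicate 2, 0.14 without day 20 replicate 3 and 0.46 without day 20 replicate 2. The calcium handling median was 0.35 without day 10 replicate 2 and 1.01 without day 10 replicate 3. The growth signalling median lay between -0.41 without day 10 replicate 2 and -0.06 without day 10 replicate 1, and was -0.11 without day 10 replicate 3 and -0.14 without day 20 replicate 1. Without day 10 replicate 1 the glycolysis median was 0.24 and the neural median -0.21. The oxidative phosphorylation median was 0.19, 0.08 and 0.08 without day 20 replicate 1, 2 and 3. In these arrays the mean poly-A spike level was 5.52 at day 10 and 6.40 at day 20.

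Over all genes, 2545 passed the test between day 20 and day 10, 1328 higher and 1217 lower at day 20, of which 1078 differed at least 2-fold (740 higher, 338 lower). The count was 4646 without day 10 replicate 3, and between 1014 and 1640 without day 10 replicate 1 or 2 or any 1 of the day 20 arrays. Array weights gave 5612 genes and a fit of only the 6 arrays compared 1326. At least 2-fold, array weights gave 1744 and the poly-A spike covariate 1787. The 2-fold count was 1866 without day 10 replicate 3 and 649 without day 20 replicate 2. Of the 32 lists, 16 were shifted (10 up, 6 down), 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 13 by fry.

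The comparison of day 30 with day 20 covers the later 10 days. Few genes passed the test. Fmo1, a flavin monooxygenase gene, rose by 4.01 (SE 0.57, adjusted p = 0.045), from 6.06 ± 1.27 to 10.07 ± 0.53 (SD, n = 3), and the nuclear noncoding RNA Neat1 by 3.15 (SE 0.34, adjusted p = 0.023). Gpm6b rose by 3.21 and the matrix proteoglycan genes Ogn and Prelp by 3.19 and 3.18. Sox11, a transcription factor gene of progenitor cells, fell by 2.07. The other falls named by the rule were the connexin gene Gja4 (-1.32), Igf2bp1 (-1.06), Adamts3 (-0.95) and Rps6ka6 (-0.92). Each of these 10 genes lost its call without several of the single arrays, with adjusted p-values of up to 0.21. Tnni3 differed by 0.40 (adjusted p = 0.72), Myl2 by 1.07 (adjusted p = 0.65) and Mki67 by -1.04 (adjusted p = 0.66). Without day 20 replicate 1, Tnni3 was at 0.25 and Mki67 at -0.54, and without day 20 replicate 2 Myl2 was at 0.30.

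Between day 20 and day 30 lists were shifted in both directions. The fibroblast and matrix list was shifted upward (median 0.55, adjusted p = 3.5e-06, adjusted p = 0.48 with an estimated correlation). Over all genes 1 member passed, Thy1 at 2.76, which was singled out after its values were seen, and 4 passed when adjusted over the list alone. The interferon list was shifted upward with 1 rise, Xaf1 at 1.47, and 2 over the list alone (median 0.32, adjusted p = 2.1e-05, adjusted p = 0.28 with an estimated correlation). Cholesterol synthesis was shifted upward with no member past the test over all genes and 1 over the list alone (median 0.53, adjusted p = 0.00019, adjusted p = 0.94 with an estimated correlation). The antioxidant list was shifted upward with 1 rise, Gstm1 at 1.24, and 3 over the list alone (median 0.30, adjusted p = 0.0015, adjusted p = 0.48 with an estimated correlation). The cell cycle list was shifted downward with no member past either test (median -0.76, adjusted p = 2.8e-05, adjusted p = 0.94 with an estimated correlation). Growth signalling was shifted downward with 1 fall, Igf2bp1, and 3 over the list alone (median -0.18, adjusted p = 0.0089, adjusted p = 0.28 with an estimated correlation). Ribosomal proteins (median -0.08, adjusted p = 0.0089, adjusted p = 0.82 with an estimated correlation) and glycolysis (median -0.24, adjusted p = 0.029, adjusted p = 0.94 with an estimated correlation) were shifted downward with no member past either test. Cell cycle and ribosomal proteins missed the threshold without day 20 replicate 1 (adjusted p = 0.11 and 0.14), and glycolysis without each of 4 arrays (highest adjusted p = 0.22), namely day 20 replicates 2 and 3 and day 30 replicates 2 and 3. The cell cycle median was -0.40 without day 20 replicate 1 and -1.20 without day 20 replicate 2. The glycolysis median was -0.39 without day 20 replicate 1 and -0.15 without day 20 replicate 2. The growth signalling median was -0.12 without day 20 replicate 2 and -0.08 without day 30 replicate 1. The ribosomal median was -0.05 without day 20 replicate 1, and the fibroblast and matrix median 0.36 without day 20 replicate 3.

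In this later interval 61 of 18193 genes passed, 53 higher and 8 lower at day 30, of which 46 differed at least 2-fold (43 higher, 3 lower). The count was 160 without day 10 replicate 3 and between 5 and 36 without any 1 of the other 8 arrays. Array weights gave 311 genes, the replicate block 33, genes above the 40th percentile 30 and the poly-A spike covariate 20, and 122, 32, 30 and 18 at least 2-fold. The 2-fold count was 82 without day 10 replicate 3 and between 5 and 35 without any 1 of the others. Of the lists, 8 were shifted (4 up, 4 down); with an estimated correlation the number was 0 (3 at an unadjusted p under 0.05), and by fry it was 0 (5 at an unadjusted p under 0.05), and among genes above the 40th percentile it was 5. Day 30 replicate 2, with its low 18S signal, belongs to this comparison, and the counts without it were 17 and 16.

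**Figure D3:**
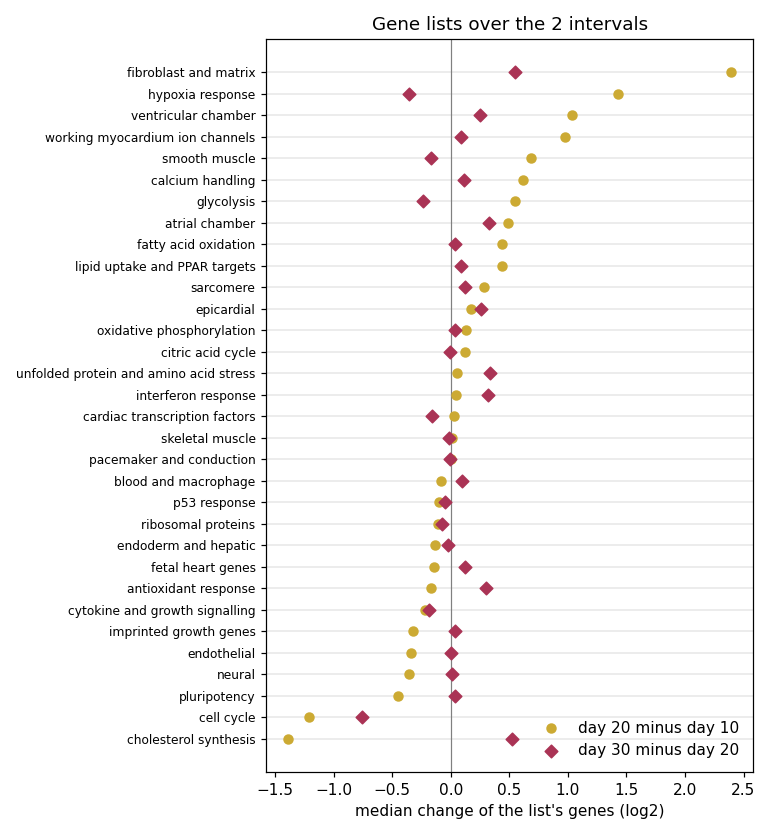
Median log2 change (horizontal axis) of the genes of each of the 32 lists (vertical axis) from day 10 to day 20 (circles) and from day 20 to day 30 (diamonds), ordered by the earlier change. The fibroblast and matrix list is at 2.39 and 0.55, and cholesterol synthesis at -1.39 and 0.53.

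A test over all 3 ages found 3189 genes that differed between any of them (limma's moderated F test with Benjamini-Hochberg adjustment). The count was 5047 without day 10 replicate 3, 1932 without day 10 replicate 2, 2119 without day 30 replicate 1 and 2071 without day 30 replicate 3, and array weights gave 6429. Whether the change of a gene differed between the 2 intervals was tested directly, as the later change minus the earlier one. Fbln5 (-6.52, SE 0.93, adjusted p = 0.035), Lox (-6.26, SE 0.77, adjusted p = 0.022) and the elastin gene Eln (-6.18, SE 0.73, adjusted p = 0.018) rose early, to day 20 levels of 12.54, 11.87 and 12.51. Their day 30 arrays ran from 12.49 to 13.09, from 11.42 to 12.77 and from 11.44 to 12.82. Igfbp3 (4.05, SE 0.61, adjusted p = 0.042), Idi1 (3.40, SE 0.39, adjusted p = 0.016) and Capn6 (3.31, SE 0.51, adjusted p = 0.044) were lower at day 20 than at both other ages. In all, 87 genes differed between the intervals: 34 had a rise followed by a fall in their means, 17 a fall followed by a rise, 25 rose and 11 fell in both. This count was 1725 without day 10 replicate 3, 0 without day 20 replicate 2 (1635 at an unadjusted p under 0.05), 1 without day 20 replicate 3, 1912 with array weights, 580 with the poly-A spike covariate, and between 27 and 47 without day 20 replicate 1 or any 1 of the day 30 arrays.

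Pairs of genes for alternative forms of the same heart protein were compared within each array. Since the signals of different probe sets have no common scale, only the change of their log2 ratio is read. The ratio of Tnni3 over Tnni1, the cardiac and slow skeletal troponin I genes, went from -3.04 ± 0.57 at day 10 to -0.44 ± 0.15 at day 20 and -0.06 ± 0.04 at day 30 (SD, n = 3, exact permutation test over the 3 ages, p = 0.0036, the smallest that the 280 distinct splits can give, adjusted p = 0.018 over 5 pairs). Tnni1 itself differed by -0.12 between day 30 and day 10 (adjusted p = 0.52), and by -0.04 and -0.20 without day 10 replicate 2 or day 30 replicate 1. The ratio of Cox7a1 over Cox7a2, heart and general forms of an oxidase subunit, went from -4.11 ± 0.56 to -2.74 ± 0.80 and -2.57 ± 0.18 (SD, n = 3, exact permutation p = 0.032, adjusted p = 0.080, and adjusted p = 0.018 without day 20 replicate 2). No change past the threshold was found for Myh6 over Myh7 (-0.49 ± 0.32, -0.17 ± 0.42 and -0.58 ± 0.13; SD, n = 3, exact permutation p = 0.31, adjusted p = 0.39), Myl2 over Myl7 (-1.77 ± 0.84, -1.33 ± 1.43 and -0.19 ± 0.26; SD, n = 3, exact permutation p = 0.19, adjusted p = 0.32) or Pfkm over Pfkp (-1.18 ± 0.53, -1.12 ± 0.32 and -0.79 ± 0.41; SD, n = 3, exact permutation p = 0.52, adjusted p = 0.52).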

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

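The list test of the difference between intervals and the fit with the poly-A spike covariate were added after the data were seen. The difference between the later and the earlier 10 days was tested directly, and 87 genes differed between the intervals at an adjusted p of 0.05 (limma). Of 100 drawn splits of the 9 arrays, 6 gave a count as large, the real split included, so that chance cannot be excluded for this count. The highest other split gave 4215 genes. It placed the 3 day 10 arrays together as the middle group, which points to a structure of the samples, the distance of day 10 from both later days. The count was 1725 without day 10 replicate 3, 0 without day 20 replicate 2 (1635 at an unadjusted p under 0.05 with limma) and 1 without day 20 replicate 3. The 6 genes named by the rule were Igfbp3 (4.0521), Idi1 (3.3968), Capn6 (3.3103), Fbln5 (-6.5194), Lox (-6.2631) and Eln (-6.1818), in log2 of the later minus the earlier change. Each lost its call without at least 3 single arrays.

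Of the 32 lists, 10 differed between the intervals with camera at the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.44 with an estimated correlation, 2 lists at an unadjusted p under 0.05), and 0 by fry. The medians of the later minus the earlier change were 1.8551 for cholesterol synthesis, -1.8471 for hypoxia, -1.2553 for fibroblast and matrix, -0.3281 for fatty acid oxidation, -0.8654 for glycolysis and 0.8150 for pluripotency. They were -0.6962 for ion channels, -0.7343 for calcium handling, -0.2476 for lipid uptake and 0.3515 for neural genes. The lipid uptake list missed the threshold without day 20 replicate 3 (adjusted p = 0.060), and the neural list without day 20 replicate 1 or day 30 replicate 1 (highest adjusted p = 0.068). Without day 10 replicate 1 the hypoxia median was -1.23, glycolysis -0.55, lipid uptake -0.16 and neural 0.23. Lipid uptake was -0.41 without day 10 replicate 3 and -0.38 without day 20 replicate 1. Fatty acid oxidation was -0.58 without day 20 replicate 1 and -0.19 without day 20 replicate 3, calcium handling -0.38 without day 10 replicate 2 and -0.47 without day 20 replicate 3, and pluripotency 1.26 without day 20 replicate 2. Of the 100 drawn splits, 53 gave as many lists, and the highest other gave 18, so that chance cannot be excluded for the number of lists.

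Cholesterol synthesis genes fell from day 10 to day 20 (median -1.39), and the list's median was 0.53 higher at day 30 than at day 20. If a single array decided the interval difference of 1.8551, that difference would be lost without it. Over the 9 fits without an array it lay between 1.5410 (without day 10 replicate 2) and 2.1476. Most of the interval difference is the early fall, so its size does not test the later rise by itself. With the poly-A spike level as a covariate the interval difference was 1.8869. That fit keeps a mean for each day, so its spike slope rests on differences between arrays of the same day. These were mostly between day 10 replicate 1 (6.23) and replicates 2 and 3 (5.24 and 5.09). The fit therefore cannot settle whether the amount of RNA labelled contributed to the differences between days. Medium change, cell density and other culture conditions were not tested, and no biological explanation was tested.

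Probe sets without a single gene name entered none of the comparisons of genes. Of these 10092 probe sets, 518 passed the test between day 30 and day 10, 231 higher and 287 lower at day 30.

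For the comparisons of pairs of days, 3 arrays against 3 make 10 splits, which cannot give a share under 0.05. As many genes as in the real split were found in 1 of 10 splits, the real one, for each of the 6 gene counts. Every other split mixes the days, which puts their difference into the spread and lowers the count. The gap between the real and the other counts is therefore no measure of support. The real counts and the highest others were 2545 and 1 genes for day 20 against day 10 (1078 and 1 at least 2-fold), 61 and 0 for day 30 against day 20 (46 and 0), and 3841 and 0 for day 30 against day 10 (1628 and 0). For lists, 2, 5 and 1 of the 10 splits gave as many, with real and highest other numbers of 16 and 16, 8 and 15, and 18 and 15. For any difference between days, 1 of 100 drawn splits, the real one, gave as many genes (3189, highest other 2017). A random grouping of these arrays is therefore an unlikely source of that count. The highest other split kept the 3 day 10 arrays together, so the distance of day 10 carries part of it. The splits treat all arrays as exchangeable, while the labels do not say whether replicates were separate differentiations. The test therefore cannot tell an effect of age from differences between single cultures.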

How the results depend on the processing

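The fit with the poly-A spike level as a covariate and the list test of the difference between intervals were chosen after the data were seen. Over 22 alternatives, 3536 of 3892 gene values, 2542 of 2740 list values, 68 of 69 pair values and 24 of 24 RNA quality values kept their side of the threshold. Those past the threshold also kept their direction. Values that passed in neither fit were counted as kept even where their sign changed. Of the gene values, 295 lost and 60 gained a call, of the list values 116 and 80, and 1 pair value gained one. With the covariate, camera's direction turned for the interval difference of the p53 list (median 0.0114 without and 0.9828 with it) and of the endothelial list (0.3703 and -0.4985), of which only the endothelial median changed sign, while Epcam was at -0.0014 between day 30 and day 10 with the mean of its probe sets. Array weights gave 5612, 311 and 6126 genes for day 20 against 10, day 30 against 20 and day 30 against 10. They gave 1744 and 122 at least 2-fold in the first pair of these comparisons, 6429 over any days and 1912 between intervals. The weights were 0.47, 2.68 and 0.29 for day 10 replicates 1, 2 and 3, so the day 10 mean rests largely on replicate 2 there. The spike covariate gave 1787 genes at least 2-fold for day 20 against 10, 20 and 18 genes for day 30 against 20 (all and at least 2-fold), 580 genes between intervals and 16 lists between intervals. Only the arrays of the days compared gave 1326 genes for day 20 against 10 and 2654 for day 30 against 10. There fewer arrays estimate the spread, and the less variable arrays of the remaining day no longer enter it. These reasons cannot be told apart here. Genes above the 40th percentile gave 30 genes, 30 at least 2-fold and 5 lists for day 30 against 20. An estimated correlation in camera gave 0 lists in each comparison of days and 0 between intervals (5, 3, 6 and 2 at an unadjusted p under 0.05), and fry 0 for day 30 against 20 (5 unadjusted). With only probe sets without a suffix, 4 isoform pairs were measured and 0 passed the exact permutation test at an adjusted p of 0.05 (lowest adjusted p = 0.16, Cox7a1 over Cox7a2). Tnni3 over Tnni1 was not among the 4, since Tnni1 was not measured there, so its change was not tested in that setting. Apart from the causes given, the cause was not tested.

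Without each array in turn, the genes changed ranged from 1014 to 4646 for day 20 against 10 (649 to 1866 at least 2-fold), from 5 to 160 for day 30 against 20 (5 to 82), and from 2572 to 5084 for day 30 against 10 (1326 to 2140). They ranged from 1932 to 5047 over any days and from 0 to 1725 between intervals, with 10 to 16 lists between intervals and 1 to 2 isoform pairs. The highest count in each of these came without day 10 replicate 3, except for the pairs (day 20 replicate 2). With the replicate number as a replicate block, 33 genes passed for day 30 against 20, 2417 for day 20 against 10, 3614 for day 30 against 10 and 74 between intervals. Whether the numbers pair the arrays was not settled. Of 9 correlations of deviations between arrays of the same number, 3 were over 0.1 (range -0.15 to 0.43). These were replicate 1 between day 10 and 20 (0.25) and replicates 2 and 3 between day 20 and 30 (0.43 and 0.30). In 8 of 18 cases an array correlated best with its own number, and no chance level was computed. The alternatives with another pseudocount were not run, since the values were already log2. Signal over background is among the limits, since differences of dim probe sets are compressed.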

Other observations

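The test of a lower share of cardiomyocytes, the fit with the poly-A spike covariate and both tests of the spread at day 10 were chosen after the results were seen. Fibroblast and matrix genes rose after day 10 by a median of 3.44 by day 30, and 0 of the 22 genes stand in another list. A lower share of cardiomyocytes that raised markers of every other cell type alike would keep the list near the other lists. The list stood 2.4135 (SE 0.443) above the nearest of them, smooth muscle. In that list Cnn1 and Acta2 fell, and Acta2 is also in the fetal heart gene list. Of the blood genes, Ptprc stayed between 3.44 and 3.85 in all arrays, while Lyz2 was higher at day 30. Lists with such members need not follow the share of other cell types. The excess therefore cannot settle whether such an even rise took place. A lower share that came with more fibroblast-like cells alone would not be seen by this test. With the poly-A spike level as a covariate, 18 of 22 genes passed the test upward, and the list's median was 3.74. That fit takes its spike slope from differences between arrays of the same day, mostly among the 3 day 10 arrays. It therefore cannot settle whether the amount of RNA labelled contributed, which stays open. Fibroblast-like cells becoming more common is a candidate explanation. Of 4 list members picked for this test, which do not encode matrix proteins, 3 rose in limma. They were Thy1 by 3.69 (adjusted p = 0.00014), Tcf21 by 2.07 (adjusted p = 0.041) and Ddr2 by 0.67 (adjusted p = 0.010), while Pdgfra differed by 1.95 (adjusted p = 0.073). Ddr2 reached only 6.30 at day 30, under the median of all genes (6.63). Other such members, such as Vim, were not counted. Since the 4 belong to the list in which 18 of 22 genes rose, they give little separate support. Puromycin, given from day 7, was meant to remove cells that do not use the Ncx1 promoter, but how completely it did so was not tested. Matrix production by the cardiomyocytes themselves was not tested and stays open.

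Day 10 arrays spread more widely than the later ones. Replicates 2 and 3, which share a low poly-A spike level, differed by a root mean square of 0.547, which is 0.0972 more than replicates 1 and 2. These are distances between 3 single arrays with no measure of their spread, so the amount of RNA labelled stays open. Cultures at different points of a shared time course may account for part of the spread, which the same 3 arrays cannot settle. Across 18193 genes, which are not independent replicates, replicate 3 minus replicate 1 correlated with the day 20 mean minus replicate 2 (r = 0.3772, Spearman 0.397). Replicate 2 minus replicate 1 against the change from replicate 3 gave r = 0.0454, replicate 3 minus replicate 2 against the change from replicate 1 gave r = 0.3616, and not all lists followed: between replicates 3 and 1 the epicardial, pluripotency and endothelial lists differed by -1.40, 0.50 and 0.998, against changes of 0.17, -0.45 and -0.34 from day 10 to day 20.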
